A study of Mus musculus with 12 samples.

How the data were processed

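Poly(A) RNA of stromal cells sorted from mouse thymus was amplified with a SMARTer ultra-low input protocol and sequenced, per the labels' protocols. The 12 libraries fell into 4 groups of 3 by their titles: tomato+ VEC, tomato- VEC, tomato+ cTEC and tomato- mTEC. The submitters' processing notes name TopHat2 2.0.10 and the genome build mm9. The read counter, the gene annotation and any filter are not given in the sources used here. The deposited table gives a raw read count per gene symbol and library, per the file headers, and these counts are whole numbers with a different total in each column. It also gives deposited RPKM values, per the file headers. For all 180417 values tested, the RPKM equalled the count divided by the column total and by a single length per gene, within a relative tolerance of 1e-06. No coordinates are printed, because the reference at hand was of another build.

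The table held 23306 gene symbols, 1704 of them with no count, and no summary entries. Total counts per library were 8388869 to 11807130. Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr (minimum count 10), which left 14792, and libraries were scaled by TMM. All 12 libraries entered a quasi-likelihood fit with a term per group, so that the groups shared a spread estimate with 8 residual degrees of freedom. The common dispersion was 0.624, a biological coefficient of variation of 0.790. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called, with no fold threshold. The comparisons were tomato+ against tomato- VEC, tomato+ cTEC against tomato- mTEC, tomato+ VEC against tomato+ cTEC, and the difference between the first and the second. Genes called in the same direction in the first and the second were counted beside the number for independent lists.

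Values per group are mean ± SD of TMM-normalised CPM. For a gene with 0 counts in a group, the fold is a lower bound against a floor of 3 counts over the group. For 1 to 3 counts the ratio is given with a 95% counting interval. Among the tested genes 50 shared all their counts with another symbol.

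The 33 gene lists covered endothelial subtypes, epithelial subtypes, niche and adhesion genes, signalling responses, antigen presentation, metabolism, cell cycle, stress and markers of other cell types. They held 359 distinct genes, 356 of them in the table. Some genes are in several lists, so calls of such lists are not separate evidence. The arterial and Notch lists share Hey1, Dll4 and Jag1, and the venous and homing lists share Selp, Vcam1 and Madcam1. The cortical and niche lists share Cxcl12, Dll4, Ccl25 and Il7. Lists with at least 3 tested members (32) were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. The test was repeated with an estimated correlation and with fry. Members were adjusted over all genes and over the list alone. The B cell list had 2 tested members and is given as values.

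Genes were named by a fixed rule. It took Kitl, Pecam1, Epcam and Enpep. It also took the 8 largest called changes in each direction with a mean of at least 5 CPM and no overlap of the libraries. From these 8, symbols of unnamed gene models and of immunoglobulin and T-cell receptor segments were left out. It further took up to 3 members with the smallest p in the direction of each called list. Last, it took the 8 genes with the smallest larger p among those higher, and among those lower, in both reporter contrasts. Other list members are named in the counts of their lists. Some genes of the lists and of the overlap are not reported here. Further genes named from the overlap of the contrasts or from the marker lists were chosen after their values were seen. The groups, comparisons, tests, lists, naming rule and alternatives were fixed before the data were examined, except where stated.

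The alternatives were DESeq2 1.42.0, limma voom, relative log expression scaling, no low-count filter, at least 5 CPM in 3 libraries, only the 6 libraries compared, the replicate number as a block, robust dispersions, an absolute log2 fold change of at least 1, limma-trend on log2(RPKM + 1), and leaving out each library. The counts of differences and overlaps were run under fewer of these. Scripts were tested on simulated counts with 50 genes changed at each of 4 fold sizes. With 14070 genes simulated for the VEC comparison, edgeR recovered 2%, 26%, 64% and 78% of genes changed 2-fold, 4-fold, 8-fold and 16-fold, and 7.61% of its calls were false. For the TEC comparison (14234 genes) it recovered 0%, 22%, 42% and 66% with 2.99% false. For the comparison of the tomato+ populations (14045 genes) it recovered 0%, 34%, 50% and 76% with 2.44% false. DESeq2 gave 37.6%, 42.3% and 38.3% false calls in the same simulations. Each was a single draw that used the spread estimates of edgeR, which may favour edgeR over the other tools. In each comparison camera, with either correlation, and fry called the list that was changed and 0 of 30 unchanged lists. Genes were simulated independently, so this does not test the preset correlation on lists whose members vary together.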

Results

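The series measured polyadenylated RNA in stromal cells sorted from the thymus of C57BL/6 mice that carry a tomato reporter for Kit ligand. Kit ligand, the product of Kitl, binds the receptor tyrosine kinase Kit on early blood and T-cell progenitors, and the series title asks which endothelial and epithelial cells provide it. CD31+ EpCAM- cells were sorted as vascular endothelial cells (VEC) with or without tomato signal. EpCAM+ CD31- cells were sorted as Ly51+ UEA1- tomato+ cortical epithelial cells (cTEC) and as UEA1+ Ly51- tomato- medullary epithelial cells (mTEC). Each of the 4 groups had 3 libraries, with total counts of 8388869 to 11807130. Between 13406 and 14346 genes had a count in an endothelial library, 15086 to 15605 in a cTEC library and 16708 to 17015 in an mTEC library. The first principal component held 49.3% of the variance and separated endothelial from epithelial libraries, the second (13.1%) separated cTEC from mTEC, and the third (8.42%) separated tomato+ from tomato- VEC. On the third, tomato+ VEC replicate 3 stood at 32.6, against 99.9 and 110 for replicates 1 and 2 and -109 to -67.6 for tomato- VEC. Replicates of every group differed by more than sampling noise. The chi-square per degree of freedom was 86.7 to 137 between endothelial replicates and 41.4 to 60.0 between epithelial ones. The groups shared a spread estimate per gene, so p-values may be too small in VEC and too large in TEC. Nothing in the labels says that replicates came from separate animals, so p-values measure only the spread between these samples. Counting intervals and floors cover counting error only.

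Kitl itself was present in all 4 groups. It stood at 1043 ± 436 CPM (normalised counts scaled to library size; SD, n = 3) in tomato+ VEC, 438 ± 40.7 in tomato- VEC, 222 ± 35.3 in tomato+ cTEC and 22.0 ± 15.9 in tomato- mTEC. The 3 tomato+ endothelial libraries were all above the 3 tomato- ones, a separation that 10% of splits of 3 against 3 give by chance, but the difference did not pass (log2 1.25, SE 0.53, edgeR adjusted p = 0.266). Kitl was higher in tomato+ cTEC than in tomato- mTEC (log2 3.33, SE 0.57, edgeR adjusted p = 0.0053) and higher in tomato+ VEC than in tomato+ cTEC (log2 2.23, SE 0.54, edgeR adjusted p = 0.0114). All 3 tomato- VEC libraries were above all 3 tomato+ cTEC libraries, by log2 0.98 (SE 0.52), a difference that did not pass (edgeR adjusted p = 0.230; exact permutation p = 0.1, the smallest that 10 splits can give). The reporter contrasts of Kitl in VEC and in TEC differed by log2 -2.08 (SE 0.74), which did not pass either (edgeR adjusted p = 0.156).

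Of the other sorting genes, Pecam1, which encodes CD31, was at 2788 ± 501 CPM in tomato+ VEC and 4213 ± 1074 in tomato- VEC (SD, n = 3), and at 7.54 ± 5.41 in mTEC. In tomato+ cTEC it was at 36.8 ± 61.8 CPM (SD, n = 3), because replicate 2 held 108 CPM against a mean of 1.09 in the other libraries of the group. Epcam stood at 239 ± 23.4 CPM in cTEC and 352 ± 14.4 in mTEC, against 0 counts in tomato+ VEC and 3 in tomato- VEC over 3 libraries each. Enpep, which encodes Ly51, was at 89.6 ± 21.3 CPM in cTEC and 17.2 ± 18.0 in mTEC (SD, n = 3), a difference that did not pass (log2 2.38, SE 1.38, edgeR adjusted p = 0.391). In mTEC, sorted as Ly51-, replicates 1 and 3 held 15.8 and 35.8 CPM of Enpep against 0 in replicate 2, and 35.5 and 26.1 CPM of Kitl against 4.53.

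**Figure D1:**
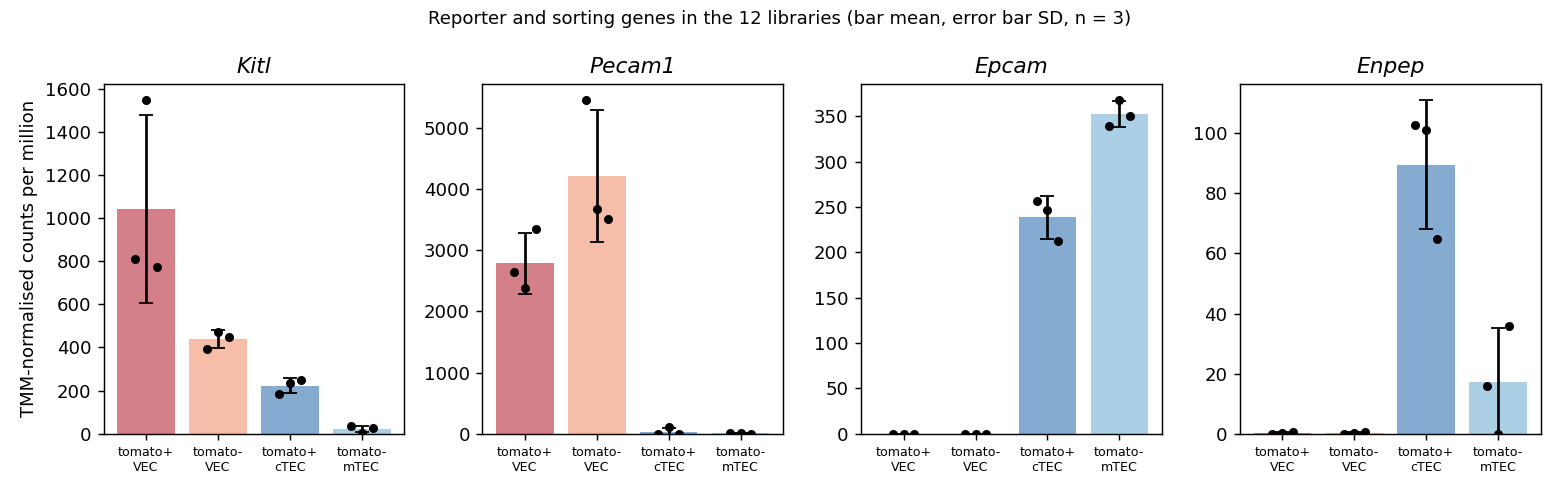
TMM-normalised CPM of Kitl, Pecam1, Epcam and Enpep (vertical axes, linear) in the 4 sorted groups; bars are means, error bars SD, and points the 3 libraries. Mean Kitl is 1043 in tomato+ VEC, 438 in tomato- VEC, 222 in cTEC and 22.0 in mTEC.

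The first comparison asked what distinguishes endothelial cells with and without the Kit ligand reporter. Arterial genes as a list were higher in tomato+ VEC, and venous and lymphatic genes were higher in tomato- VEC. Efnb2, the arterial ephrin, stood at 507 ± 109 CPM in tomato+ against 59.1 ± 30.4 CPM in tomato- VEC (SD, n = 3), and Hey1, an arterial target of Notch, was 653-fold higher (counting interval 223 to 3165, from 3 counts in tomato- VEC). In the other direction, Darc, the atypical chemokine receptor of venules, stood at 170 ± 132 against 2886 ± 736 CPM, and Lyve1, a lymphatic marker, was at least 491-fold lower, with 0 counts in tomato+ VEC and 1511 in tomato- VEC. Of 14792 genes tested, 84 rose and 160 fell in tomato+ VEC (edgeR, Benjamini-Hochberg adjusted p under 0.05). Without tomato+ VEC replicate 3, 394 genes passed, and with only the 6 endothelial libraries in the fit 112 passed. The count was 1253 by DESeq2, 601 by limma voom and 473 by limma-trend on log2(RPKM + 1).

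Of 12 tested arterial genes 2 rose (Efnb2 and Hey1) and 10 did not pass, while 5 rose when adjusted over the list alone. The list as a whole was higher (camera adjusted p = 4.81e-10, and adjusted p = 0.0181 with an estimated correlation). Efnb2 rose by log2 3.10 (SE 0.39, edgeR adjusted p = 0.00194) and Hey1 also passed (edgeR adjusted p = 0.00166). Neither call was lost when any library was left out. Jag1, a Notch ligand, had log2 1.00 (SE 0.25) and did not pass (edgeR adjusted p = 0.0656). Of 13 tested venous and post-capillary genes 2 fell (Darc and Vcam1) and 11 did not pass, while 11 fell when adjusted over the list alone (camera adjusted p = 1.11e-08, and adjusted p = 0.0181 with an estimated correlation). Darc had log2 -4.09 (SE 0.85, edgeR adjusted p = 0.0334) and Vcam1, an adhesion molecule for progenitors, -1.48 (SE 0.33, edgeR adjusted p = 0.0490). Selp, which encodes P-selectin, was at 76.0 ± 69.8 against 1252 ± 245 CPM (SD, n = 3) without passing (log2 -4.04, edgeR adjusted p = 0.0652). It passed without tomato+ VEC replicate 3. The Darc call was lost without tomato+ VEC replicates 1 or 3 or tomato- VEC replicates 1 or 2 (edgeR adjusted p up to 0.0923). The Vcam1 call was lost without tomato+ VEC replicates 1 or 2, any tomato- VEC library or cTEC replicate 2 (edgeR adjusted p up to 0.129), and with relative log expression scaling (0.0545).

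Of 6 tested lymphatic genes 2 fell, Lyve1 (edgeR adjusted p = 0.00914) and Pdpn, which encodes podoplanin (log2 -6.97, SE 0.99, edgeR adjusted p = 0.00446). Another 4 did not pass and 3 fell when adjusted over the list alone (camera adjusted p = 0.000383, and adjusted p = 0.0311 with an estimated correlation). Pdpn stood at 0.201 ± 0.166 against 25.5 ± 22.4 CPM (SD, n = 3), and Reln had log2 -5.28 without passing (edgeR adjusted p = 0.201). Of 10 capillary genes 2 rose, Rgcc (log2 3.94, SE 0.54, edgeR adjusted p = 0.00358) and Lpl, the lipoprotein lipase (6.47, SE 1.22, edgeR adjusted p = 0.0202), 8 did not pass and 3 rose when adjusted over the list alone. Rgcc stood at 1286 ± 70.9 against 83.7 ± 58.3 CPM (SD, n = 3). The capillary list was called higher (camera adjusted p = 0.000383) but not with an estimated correlation (adjusted p = 0.348). Car4, Cd300lg and Plvap of this list had log2 -0.32, 0.08 and -1.39 without passing. Lpl was lost without tomato- VEC replicates 1 or 2 (edgeR adjusted p up to 0.0801).

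Another 7 lists were called by camera and lost with an estimated correlation. Flow-responsive genes were higher (adjusted p = 0.0199, and adjusted p = 0.348 with an estimated correlation). Of 6 tested, Thbd, which encodes thrombomodulin, rose (log2 2.07, SE 0.27, edgeR adjusted p = 0.00258), 5 did not pass, and adjusted over the list alone 4 rose and 1 fell. Notch pathway genes were higher (adjusted p = 0.00363, and adjusted p = 0.0809 with an estimated correlation), with Hey1, also in the arterial list, the only 1 of 12 to pass and 3 higher when adjusted over the list alone. Among 12 basement membrane and matrix genes (adjusted p = 0.0234, and adjusted p = 0.356 with an estimated correlation) Fn1, which encodes fibronectin, rose from 7.18 ± 6.19 to 222 ± 32.5 CPM (SD, n = 3; log2 4.95, SE 0.79, edgeR adjusted p = 0.00914), and 1 rose when adjusted over the list alone. Dissociation stress and immediate early genes were higher in tomato+ VEC (adjusted p = 0.00126, and adjusted p = 0.481 with an estimated correlation), with Hspa1a the 1 of 14 to pass (log2 4.17, edgeR adjusted p = 0.0323) and 6 higher when adjusted over the list alone. The Hspa1a call was lost without tomato+ VEC replicates 1 or 2 or any tomato- VEC library (edgeR adjusted p up to 0.0794).

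Lower in tomato+ VEC were the lists of progenitor homing adhesion genes (adjusted p = 0.0234, and adjusted p = 0.302 with an estimated correlation), MHC class II genes (adjusted p = 0.0234, and adjusted p = 0.521 with an estimated correlation) and glycolysis genes (adjusted p = 0.000834, and adjusted p = 0.102 with an estimated correlation). Of 10 homing genes Vcam1 and Glycam1 fell and 3 fell when adjusted over the list alone. Glycam1, a ligand of L-selectin, had 1 count in tomato+ VEC and 5829 in tomato- VEC (5677-fold, counting interval 1019 to 224233). Its call was lost without any tomato+ VEC library or tomato- VEC replicate 1 (edgeR adjusted p up to 0.119). Of 9 MHC class II genes Cd74, the invariant chain, fell (log2 -1.79, SE 0.31, edgeR adjusted p = 0.0130) and 2 fell when adjusted over the list alone. Of 14 glycolysis genes Pkm fell (log2 -1.30, SE 0.23, edgeR adjusted p = 0.0146) and 3 fell when adjusted over the list alone. The Pkm call was lost without replicate 1 of either endothelial group (edgeR adjusted p up to 0.0531). The platelet genes Pf4 and Ppbp were at 55.2 and 107 CPM in tomato- VEC replicate 1 and at or under 0.336 CPM in the other tomato- VEC libraries.

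**Figure D2:**
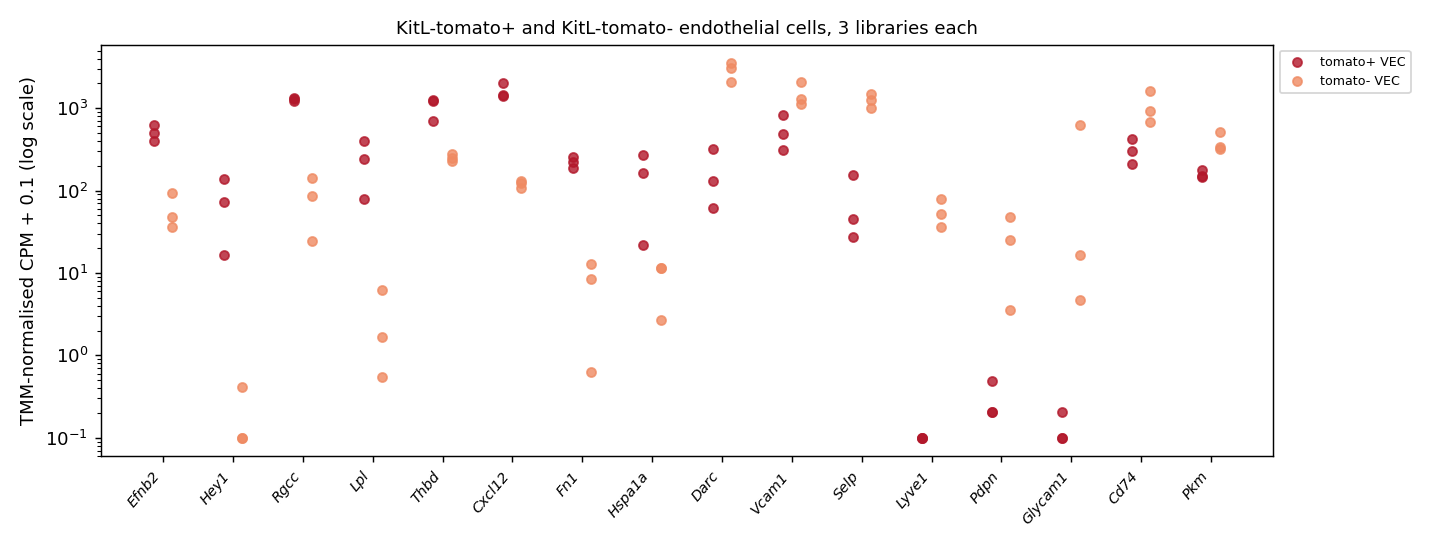
TMM-normalised CPM plus 0.1 (vertical axis, log scale) of 16 genes in tomato+ and tomato- VEC; each point is a library. Efnb2, Hey1, Rgcc and Fn1 are higher in tomato+ VEC, Darc, Lyve1, Pdpn and Cd74 in tomato- VEC, with no overlap between the groups.

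Genes with large changes were of several kinds. Higher in tomato+ VEC were Slc26a10 (144 ± 74.2 CPM against 1 count in total, 3992-fold, counting interval 716 to 157677), B4galnt1 (at least 92.8-fold), Ank3 (456-fold, counting interval 81.8 to 18006) and Nepn (90.7 ± 49.5 against 0.291 ± 0.162 CPM; SD, n = 3). Their edgeR adjusted p was 0.000234, 0.00752, 0.00407 and 0.00592, and none of these 4 calls was lost when a library was left out. Sox11, Tnfsf9 and Lrrc2 also passed (edgeR adjusted p = 0.0433, 0.0152 and 0.0461). Sox11 and Lrrc2 were lost in 6 of the leave-outs each, those of all but 1 endothelial library and of cTEC replicate 2 (edgeR adjusted p up to 0.103 and 0.132). Tnfsf9 was lost without any tomato- VEC library (up to 0.0588). Lower in tomato+ VEC were Coro1a, an actin-binding protein of leukocytes (at least 143-fold, edgeR adjusted p = 0.00953), Ccdc51 (at least 236-fold, edgeR adjusted p = 0.00818), Tmem107 (at least 122-fold, edgeR adjusted p = 0.00116) and Cpe, carboxypeptidase E (1153-fold, counting interval 395 to 5592, edgeR adjusted p = 0.0202). The Cpe call was lost without tomato+ VEC replicate 1 (edgeR adjusted p = 0.0662), and those of Fgl2 (edgeR adjusted p = 0.0394) and Alox5ap (edgeR adjusted p = 0.0482) without any of the 6 endothelial libraries (up to 0.103 and 0.0954). With only the 6 endothelial libraries in the fit, Ank3, B4galnt1, Coro1a, Tmem107, Lrrc2, Alox5ap, Fn1, Pdpn, Cd74, Pkm, Hspa1a, Glycam1 and Vcam1 did not pass (edgeR adjusted p up to 0.338).

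The second comparison set tomato+ cTEC against tomato- mTEC, so that the reporter and the cortical or medullary gate changed together and cannot be separated. The groups carried the known cortical and medullary programmes. Prss16, the thymus-specific serine protease, stood at 1075 ± 245 CPM in cTEC against 17.8 ± 2.66 CPM in mTEC (SD, n = 3), and Psmb11, the thymoproteasome subunit, at 626 ± 96.9 against 26.5 ± 11.4 CPM. Aire, the regulator of tissue-restricted antigens, stood at 160 ± 9.63 CPM in mTEC with 3 counts in cTEC (1731-fold, counting interval 592 to 8395), and the milk casein gene Csn2 at 644 ± 67.5 against 1.13 ± 1.95 CPM. In cTEC 404 genes rose and 754 fell (edgeR, Benjamini-Hochberg adjusted p under 0.05). The count fell to between 428 and 702 when any 1 of the 6 libraries was left out. It was 1973 by DESeq2, 2219 by limma voom, 2530 by limma-trend on log2(RPKM + 1) and 2487 with only the 6 epithelial libraries in the fit.

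Of 13 cortical epithelial genes 7 rose, among them Prss16 (log2 5.92, SE 0.32, edgeR adjusted p = 3.38e-06), Cxcl12 (4.91, SE 0.46, edgeR adjusted p = 0.000155) and Psmb11 (4.56, SE 0.45, edgeR adjusted p = 0.000209), while 6 did not pass and 9 rose when adjusted over the list alone. The list was higher (camera adjusted p = 3.66e-16, and adjusted p = 0.000561 with an estimated correlation). Of 15 medullary genes 9 fell, among them Aire (edgeR adjusted p = 0.000562), Ccl19, a ligand of Ccr7 (log2 -5.60, SE 0.43, edgeR adjusted p = 4.87e-05), and Tnfrsf11a, which encodes RANK (-4.68, SE 0.68, edgeR adjusted p = 0.00207), and 12 fell when adjusted over the list alone (camera adjusted p = 3.79e-16, and adjusted p = 0.00171 with an estimated correlation). All 7 tested tissue-restricted antigen genes fell, with Csn2 at log2 -9.12 (SE 1.23, edgeR adjusted p = 0.00123). Apoa4 was 436-fold lower (counting interval 149 to 2113, edgeR adjusted p = 0.00147) and Tff3 1696-fold lower (counting interval 304 to 66983, edgeR adjusted p = 0.0026). All 7 also fell when adjusted over the list alone (camera adjusted p = 1.15e-09, and adjusted p = 0.00171 with an estimated correlation). Other members of this list were too low to be tested or absent. Counts in mTEC alone can carry a gene past the filter, which favours this direction. Of 10 tuft cell genes 5 fell and 9 when adjusted over the list alone (camera adjusted p = 1.27e-06, and adjusted p = 0.00497 with an estimated correlation). Among these, Trpm5, a cation channel of taste and tuft cells, was 340-fold lower (counting interval 94.2 to 2808, edgeR adjusted p = 0.00778).

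Signals for T-cell progenitors differed between the compartments. Of 16 such genes 4 were higher in cTEC (Kitl, Dll4, Cxcl12 and Bmp4), 2 were lower (Ccl21a and Ccl19) and 10 did not pass. Adjusted over the list alone 9 rose and 2 fell (camera adjusted p = 0.00317, and adjusted p = 0.0353 with an estimated correlation). Bmp4, a bone morphogenetic protein, stood at 18.3 ± 5.15 CPM in cTEC with 1 count in mTEC (581-fold, counting interval 104 to 22934, edgeR adjusted p = 0.000209). Dll4, the Notch ligand for T-lineage commitment, stood at 36.4 ± 12.7 against 3.03 ± 2.63 CPM (SD, n = 3; log2 3.60, SE 0.77, edgeR adjusted p = 0.0167). The Dll4 call was lost without mTEC replicate 1 (edgeR adjusted p = 0.0640).

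Of 12 basement membrane and matrix genes 5 rose in cTEC, among them Sparc (log2 2.26, SE 0.32, edgeR adjusted p = 0.00172), Hspg2, which encodes perlecan (1.81, SE 0.34, edgeR adjusted p = 0.00934), and Lamb1 (2.14, SE 0.43, edgeR adjusted p = 0.0125), and 9 rose when adjusted over the list alone (camera adjusted p = 8.35e-08, and adjusted p = 0.0269 with an estimated correlation). The Lamb1 call was lost without replicate 1 of either group (edgeR adjusted p up to 0.0601), and Hspg2 did not pass with only the 6 epithelial libraries in the fit or by limma. Of 12 mesenchymal and pericyte genes Dcn, which encodes decorin, also rose in cTEC, from 241 ± 127 to 1864 ± 267 CPM (SD, n = 3; log2 2.95, SE 0.67, edgeR adjusted p = 0.0212). Adjusted over the list alone 3 rose and 1 fell, and the list was not called (camera adjusted p = 0.378). Col3a1 and Col1a2 of this list had log2 3.17 and 3.61 without passing (edgeR adjusted p = 0.0579 and 0.0890). The Dcn call was lost without cTEC replicate 1 or mTEC replicates 1 or 2 (edgeR adjusted p up to 0.0786). Of 6 genes listed as flow-responsive in endothelium 3 rose, Thbd (3.36, SE 0.29, edgeR adjusted p = 0.000102), Cav1 (2.94, SE 0.46, edgeR adjusted p = 0.00329) and Klf2 (2.85, SE 0.55, edgeR adjusted p = 0.0104), and 4 when adjusted over the list alone (camera adjusted p = 1.3e-06, and adjusted p = 0.0353 with an estimated correlation). Of 12 thymocyte genes Cd3e and Cd8a rose, as they did when adjusted over the list alone (camera adjusted p = 0.00571, and adjusted p = 0.0440 with an estimated correlation). Cd3e stood at 12.9 ± 9.89 against 0.0643 ± 0.111 CPM (SD, n = 3; edgeR adjusted p = 0.0467) and Cd8a at 11.2 ± 9.87 against 0 counts (edgeR adjusted p = 0.0368). Both calls were lost when any 1 of the 6 libraries was left out (up to 0.154 and 0.111).

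Another 7 lists were called and lost with an estimated correlation. Higher were interferon-stimulated genes (camera adjusted p = 0.00571, and adjusted p = 0.272 with an estimated correlation), stress and immediate early genes (0.000124, and adjusted p = 0.234 with an estimated correlation) and arterial endothelial genes (0.0351, and adjusted p = 0.221 with an estimated correlation). Ifit3 (log2 1.73, edgeR adjusted p = 0.00237) and Ifit1 (2.30, edgeR adjusted p = 0.0103) rose and Usp18 fell among 12 interferon-stimulated genes, while adjusted over the list alone 4 rose and 1 fell. Fosb, Egr1 and Nr4a1 rose among 14 stress genes (edgeR adjusted p = 0.0434, 0.0359 and 0.0154; 5 adjusted over the list alone), each call lost in 3 to 5 leave-outs of a single library (up to 0.166, 0.129 and 0.0640). Dll4 and Nrp1 rose among 12 arterial genes, while adjusted over the list alone 6 rose and 2 fell. Lower were venous genes (0.0351, and adjusted p = 0.221 with an estimated correlation), lymphatic genes (0.0272, and adjusted p = 0.110 with an estimated correlation), cell cycle genes (0.0272, and adjusted p = 0.290 with an estimated correlation) and erythroid genes (0.0272, and adjusted p = 0.221 with an estimated correlation). Madcam1, Bst1 and Darc fell among 13 venous genes (adjusted over the list alone 4 fell and 1 rose), and Nts and Lyve1 among 6 lymphatic genes (adjusted over the list alone 4 fell and 1 rose). No cell cycle gene passed, by edgeR either over all genes or adjusted over the list alone, and of 5 erythroid genes 0 passed, with 4 lower when adjusted over the list alone. In the erythroid list Hba-a1 and Hba-a2 shared all counts with each other, as did Hbb-b1 and Hbb-b2, so its members are not all separate. Without cTEC replicate 2, which held endothelial transcripts, the calls of Nrp1, Madcam1, Bst1, Darc and Lyve1 were lost, each also without at least 2 other libraries. Of these, only Nrp1 was higher in cTEC, the direction that such transcripts would give. Replicate 2 held 0.196 CPM of Darc and 0 of Bst1, against means of 0.132 and 0.130 in the other cTEC libraries. In mTEC, Darc stood at 2.98 ± 4.09 and Lyve1 at 2.95 ± 3.21 CPM (SD, n = 3).

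**Figure D3:**
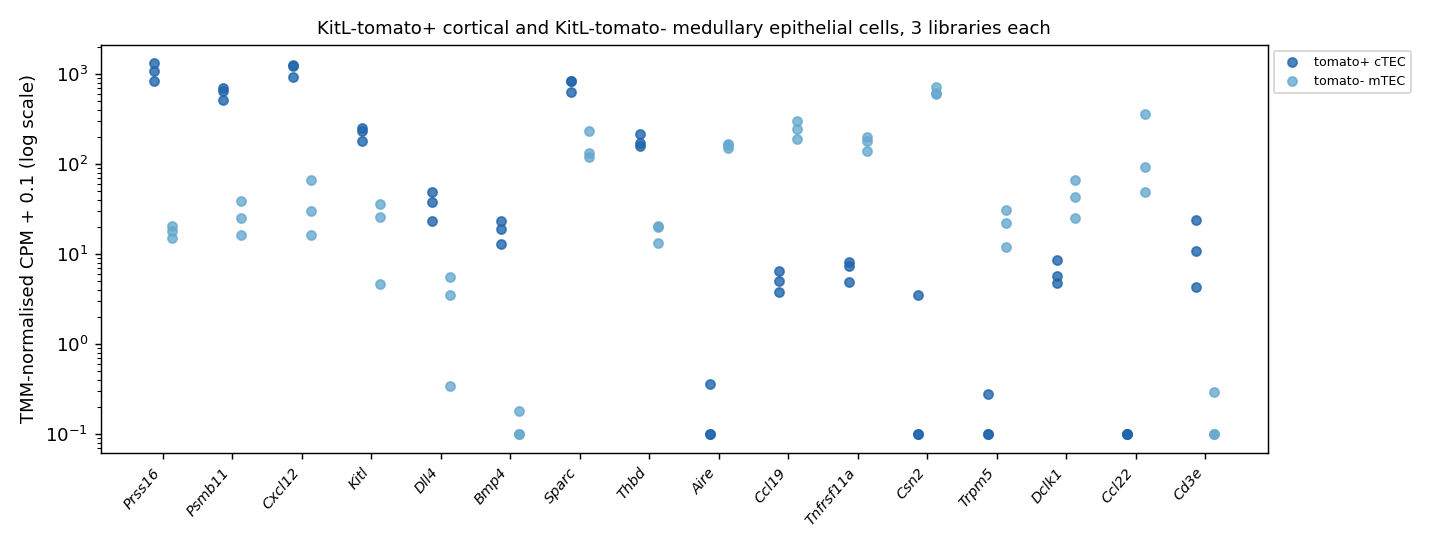
TMM-normalised CPM plus 0.1 (vertical axis, log scale) of 16 genes in tomato+ cTEC and tomato- mTEC; each point is a library. Prss16, Psmb11, Cxcl12, Kitl, Bmp4 and Sparc are higher in cTEC, and Aire, Ccl19, Tnfrsf11a, Csn2, Trpm5 and Ccl22 in mTEC, with no overlap between the groups.

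Large differences between cTEC and mTEC went in both directions. With 0 counts in cTEC, Ccl22, a ligand of Ccr4, was at least 1629-fold lower (edgeR adjusted p = 0.000951), Iapp, islet amyloid polypeptide, at least 764-fold (edgeR adjusted p = 0.000821) and Psca at least 761-fold (edgeR adjusted p = 0.00123). Rgs13, Pgc and Fcer2a were at least 1148-fold, 645-fold and 1265-fold lower (edgeR adjusted p = 0.00301, 0.00212 and 0.00522). Higher in cTEC were Prss23 (1207-fold, counting interval 334 to 9967, edgeR adjusted p = 4.87e-05), Dcdc2a (740-fold, counting interval 133 to 29248, edgeR adjusted p = 0.00579) and Phex (651-fold, counting interval 117 to 25711, edgeR adjusted p = 0.00759). None of these 9 calls was lost when a library was left out. Eda passed (edgeR adjusted p = 0.0132) and was lost without mTEC replicate 1 (0.0525), and Tm4sf5 (edgeR adjusted p = 0.0151) was lost without cTEC replicate 1 (0.0529). Prkcq, Itgb2, a leukocyte integrin chain, Adhfe1 and Gal also passed (edgeR adjusted p = 0.0283, 0.0281, 0.0220 and 0.0432). Prkcq and Itgb2 were lost without any of the 6 libraries (up to 0.0868 for each), Adhfe1 without any but cTEC replicate 3 (up to 0.0909) and Gal without any but mTEC replicate 3 (up to 0.105).

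The third comparison set the tomato+ populations of both lineages side by side. Endothelial cells carried more Kitl, basement membrane and adhesion transcripts, and cTEC carried Il7, Ccl25 and MHC class II transcripts. Il7, the cytokine for early thymocyte survival, stood at 478 ± 71.5 CPM in cTEC and had 4 counts in tomato+ VEC (0.142 ± 0.164 CPM; SD, n = 3). Cd74 stood at 27177 ± 1806 CPM in cTEC against 311 ± 108 in tomato+ VEC, and Col4a1 at 207 ± 24.0 against 1899 ± 126 CPM (SD, n = 3). In tomato+ VEC 1398 genes rose and 1841 fell (43.2% higher; edgeR, Benjamini-Hochberg adjusted p under 0.05). By limma-trend on log2(RPKM + 1), which changes the test as well as the scale, 1222 were higher and 2737 lower (30.9% higher). Scaling by total count in place of TMM moved the median of all genes by log2 -0.29 in this comparison and by -0.13 in the difference between the reporter contrasts.

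Lineage genes followed the sort. Of 12 pan-endothelial genes 11 rose, 11 also when adjusted over the list alone (camera adjusted p = 1.45e-08, and adjusted p = 0.0709 with an estimated correlation), among them Flt1 (log2 6.61, SE 0.99, edgeR adjusted p = 0.000573). Of 11 pan-epithelial genes 9 fell, 10 adjusted over the list alone (3.22e-24, and adjusted p = 0.000231 with an estimated correlation), among them Krt18 (log2 -12.24, SE 0.42, edgeR adjusted p = 1.18e-08). Of 13 cortical genes 10 fell, 10 also adjusted over the list alone with 1 higher (5.14e-17, and adjusted p = 0.000642 with an estimated correlation), among them Tbata (-13.05, SE 1.00, edgeR adjusted p = 4.26e-06). Of 15 medullary genes 8 fell and Tnfrsf11a rose, 9 and 1 adjusted over the list alone (3.4e-07, and adjusted p = 0.0456 with an estimated correlation), with Krt14 (-11.50, SE 0.60, edgeR adjusted p = 3.15e-07) and Krt5 (-8.67, SE 0.57, edgeR adjusted p = 1.62e-06) among those higher in cTEC. Arterial (4 of 12 rose, 6 adjusted over the list alone), venous (9 of 13, and 9) and capillary genes (8 of 10, and 9) were higher in tomato+ VEC (7.49e-05, 3.41e-08 and 1.43e-11, and adjusted p = 0.0240 for each with an estimated correlation). Tip cell genes (3 of 9, and 4 adjusted over the list alone) and flow-responsive genes (5 of 6 rose and 1 fell in both counts) were called (0.0215 and 0.00322) and lost with an estimated correlation (adjusted p = 0.188 and 0.0781).

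Of 16 niche signals Kitl rose and Il7, Ccl25, Ccl21a, Ccl19 and Wnt4 fell in tomato+ VEC, while adjusted over the list alone 2 rose and 5 fell (camera adjusted p = 0.0201, and adjusted p = 0.0739 with an estimated correlation). Il7 had log2 -11.53 (SE 0.91, edgeR adjusted p = 5.9e-06) and Wnt4 was 2450-fold lower (counting interval 440 to 96787, edgeR adjusted p = 8.49e-06). Of 10 homing adhesion genes 5 rose, 5 also adjusted over the list alone (0.00184, and adjusted p = 0.0456 with an estimated correlation), among them Selp (7.66, SE 1.26, edgeR adjusted p = 0.00105), Icam2 (5.04, SE 0.96, edgeR adjusted p = 0.0028) and Cd34 (5.92, SE 1.06, edgeR adjusted p = 0.0018). Of 12 matrix genes 8 rose and 1 fell, 8 and 2 adjusted over the list alone (1.83e-07, and adjusted p = 0.0253 with an estimated correlation), among them Col4a1 (3.20, SE 0.21, edgeR adjusted p = 1.65e-06) and Col4a2 (3.32, SE 0.25, edgeR adjusted p = 4.1e-06). Of 9 MHC class II genes 8 fell, adjusted over the list alone 8 fell and 1 rose (3.64e-11, and adjusted p = 0.0240 with an estimated correlation), while 6 of 10 MHC class I and immunoproteasome genes rose and 1 fell, 7 and 1 adjusted over the list alone (0.00874, and adjusted p = 0.0456 with an estimated correlation). B2m had log2 1.00 (SE 0.13, edgeR adjusted p = 0.000175) and H2-D1 0.99 (SE 0.17, edgeR adjusted p = 0.00156).

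Markers of other cell types also differed between these gates. Of 12 thymocyte genes 7 were lower in tomato+ VEC, 10 adjusted over the list alone (camera adjusted p = 0.00913, and adjusted p = 0.0456 with an estimated correlation), with Cd3g at 12.9 ± 8.25 CPM in cTEC and 0 counts in tomato+ VEC. The Cd8a call (edgeR adjusted p = 0.0173) was lost without cTEC replicate 2 (0.0523). Of 12 mesenchymal and pericyte genes 7 were lower, 8 adjusted over the list alone (0.000528, and adjusted p = 0.0240 with an estimated correlation), with Dcn at 1864 ± 267 CPM in cTEC against 8.50 ± 5.21 (SD, n = 3) and Acta2 at 203 ± 124 against 3.72 ± 1.17 CPM. Notch pathway genes (5 of 12 rose and Hey2 fell, adjusted over the list alone 7 and 1) and BMP and TGF-beta response genes (5 of 12 rose and Id2 fell, adjusted over the list alone 6 and 2) were called higher (0.0123 and 0.00966) and lost with an estimated correlation (adjusted p = 0.0709 and 0.156). Stress and immediate early genes (6 of 14 rose, 6 adjusted over the list alone) were also called (0.0103) and lost (adjusted p = 0.433 with an estimated correlation). Ier2 (edgeR adjusted p = 0.0132) was lost without cTEC replicate 3 (0.0550).

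Among the large differences in this comparison were genes with 0 counts on a side. With 0 counts in cTEC, Slc28a2 was at least 1980-fold higher in tomato+ VEC (edgeR adjusted p = 0.000323), Nepn at least 1012-fold (edgeR adjusted p = 0.000185) and Bik at least 522-fold (edgeR adjusted p = 5.69e-05). With 0 counts in tomato+ VEC, Crip3 was at least 4866-fold lower (edgeR adjusted p = 5.29e-07), Fxyd3 at least 2149-fold (edgeR adjusted p = 1.71e-06) and Epcam at least 2109-fold (edgeR adjusted p = 5.96e-07). Ccrl1, an atypical receptor for Ccl25 and other chemokines, stood at 748 ± 44.3 CPM in cTEC with 1 count in tomato+ VEC (edgeR adjusted p = 0.000645).

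The last comparison asked which genes differed in the same direction between the tomato+ and tomato- gates of both lineages. In TEC the reporter still cannot be separated from the cortical or medullary gate. In both lineages 13 genes were higher in the tomato+ gate, against 2.29 for independent lists of these sizes, and 33 were lower, against 8.16. The contrasts share no library. They share a fit, with the same filter and spread estimate per gene, so that their call lists are not independent. Overlaps in opposite directions also exceeded independent lists, with 7 genes against 4.28 and 10 against 4.37. Cxcl12, the chemokine that guides Cxcr4-bearing progenitors, rose by log2 3.77 (SE 0.43, edgeR adjusted p = 0.000938) in VEC and by 4.91 in TEC. Thbd, Rgcc, Sptbn1, Ly6a, Nr3c1, Tsc22d1 and Ccdc80 also rose in both. Nr3c1, the glucocorticoid receptor, had log2 1.32 and 1.51, and Ly6a, which encodes Sca-1, 1.43 and 1.40 (edgeR adjusted p = 0.0101 and 0.00495). The VEC calls of Nr3c1, Tsc22d1 and Ccdc80 were lost without tomato- VEC replicate 3 (and Nr3c1 without tomato- VEC replicate 1, Ccdc80 without tomato+ VEC replicate 1; edgeR adjusted p up to 0.0591, 0.0694 and 0.0625), and Ccdc80 in TEC without mTEC replicates 1 or 2 (up to 0.0666). With only the 6 endothelial libraries in the fit Ccdc80 did not pass in VEC (edgeR adjusted p = 0.338). The number higher in both was 23 without tomato+ VEC replicate 3 and 8 without cTEC replicate 2, mTEC replicate 1 or mTEC replicate 2.

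Lower in both tomato+ gates were Cd82 (log2 -3.86 in VEC and -2.50 in TEC, edgeR adjusted p = 0.000143 and 0.000562), Ctsh, which encodes cathepsin H (-7.66 and -6.05, edgeR adjusted p = 0.0004 and 0.000485), Rac2 (-4.65 and -4.41, edgeR adjusted p = 0.00216 and 0.000563), Rgs4 (-5.53 and -4.07) and the Ccl21 genes, ligands of Ccr7. Ccl21c stood at 1.10 ± 0.385 CPM in tomato+ VEC against 121 ± 71.0 CPM in tomato- VEC (SD, n = 3), and at 212 ± 89.4 CPM in cTEC against 2984 ± 718 CPM in mTEC. Ccl21c shared all its counts with Gm10591, Gm13304 and Gm21541, and Ccl21a with Gm1987, so the reads of these near-identical copies cannot be assigned to one of them. With identical symbols counted once, 29 genes were lower in both against 7.86 for independent lists. Ccl21b, at log2 -6.75 in VEC and -3.82 in TEC like Ccl21c, was not fully identical to it and was still counted apart. The VEC calls of Rac2 and Rgs4 were lost with only the 6 endothelial libraries in the fit (edgeR adjusted p = 0.163 and 0.0822). Those of Rgs4 and Ccl21c were lost by limma voom (adjusted p = 0.0601 and 0.120). The number lower in both was 20 without mTEC replicate 2.

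**Figure D4:**
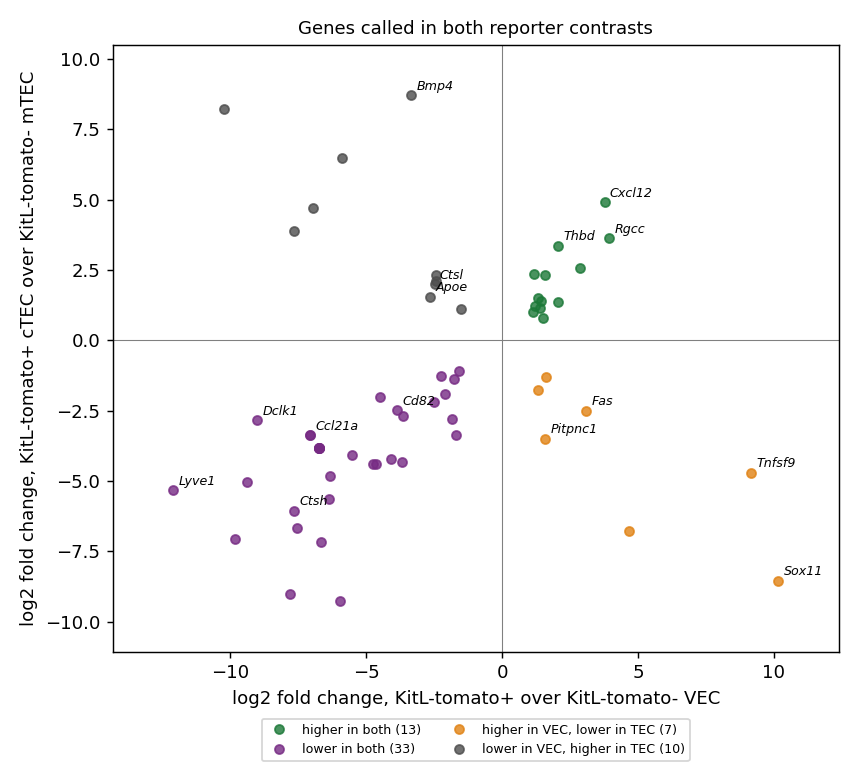
Log2 fold change of tomato+ over tomato- VEC (horizontal axis) against tomato+ cTEC over tomato- mTEC (vertical axis) for the genes called in both contrasts; each point is a gene. Of these, 13 are higher in both, 33 lower in both, 7 higher in VEC and lower in TEC, and 10 lower in VEC and higher in TEC.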

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

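The tests of carried-over cells, scaling, endothelial RNA, shared reads and leukocytes were chosen after the results were seen, and the counts of other splits were planned. Groups of 3 libraries were not tested for single libraries that stand apart.

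The reporter contrast, which in TEC is also that of cortex against medulla, differed between VEC and TEC for 456 genes. This was a test of the difference itself (edgeR, Benjamini-Hochberg adjusted p under 0.05). The count was 1418 by DESeq2 and 159 to 491 with a library left out. Among the 456 were 33 of the 110 genes named for the VEC or the TEC comparison. The fitted signs were opposite for 20, but only Sox11, Tnfsf9 and Bmp4 of these passed in both contrasts, and in VEC the log2 fold changes of Ccl19 and Trpm5 were 0.06 and 0.05. The differences in log2 fold change, VEC minus TEC, follow, with edgeR adjusted p from 0.000143 for Prss23 to 0.0480 for Ccl21c. Those of genes with 0 to 3 counts in a group are fitted values and no measure of size. The contrast was the more positive in VEC for Slc26a10 (11.94), Ccl19 (5.66), Psca (16.19), Tnfsf9 (13.88), Sox11 (18.71), B4galnt1 (10.30), Hey1 (7.72), Fcer2a (16.39), Iapp (13.25), Apoa4 (9.41), Ank3 (6.85), Tnfrsf11a (4.06), Lrrc2 (10.55), Ccl22 (14.51), Efnb2 (2.18) and Trpm5 (8.24). It was the more positive in TEC for Prss23 (-11.59), Bmp4 (-12.06), Prss16 (-5.59), Pdpn (-8.55), Tmem107 (-9.12), Ccdc51 (-12.74), Dclk1 (-6.19), Cpe (-12.34), Prkcq (-16.77), Eda (-12.18), Hspg2 (-2.19), Psmb11 (-4.52), Sptbn1 (-1.15), and Ccl21c with Gm10591, Gm13304 and Gm21541 (-2.93 each). Ccl21c and these copies share all counts and were each counted among the 33. Of the 50 genes named only for the tomato+ populations, 9, looked up after seeing the data, also passed this test: Bik (10.32), Slc28a2 (14.30), Car4 (4.35), Il7 (-6.60), Ccrl1 (-14.94), Ccl21a (-3.70), Gria3 (-10.50), Dcn (-4.40) and Fxyd3 (-5.58), with edgeR adjusted p from 0.00439 for Bik to 0.0320 for Car4. Of 100 drawn splits within VEC and within TEC, 2 gave as many genes. The highest other count was 771, from the split that kept VEC and exchanged the TEC groups, which turns the difference of the contrasts into their sum. Without it the highest was 126. The other splits mix libraries of groups that differ, which raises the spread and lowers the count. Low counts in them follow once the groups differ at all. They speak only against libraries interchangeable within each lineage, and they do not test the difference between the contrasts.

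Kitl was at 438 ± 40.7 CPM (SD, n = 3) in tomato- VEC, above the 222 ± 35.3 of tomato+ cTEC in every library, with an edgeR adjusted p of 0.230. Tomato+ cells carried into the tomato- gate would set a floor for every transcript of tomato+ VEC. Against this as the whole source, 4 of the 15 genes of the arterial, capillary and niche lists with at least 100 CPM in tomato+ VEC (Efnb2, Rgcc, Lpl and Cxcl12) had a tomato- to tomato+ ratio under the lowest ratio of Kitl. Scaling is argued against as well, since the ratio of the means was 1.68 by total count and 1.85 by relative log expression, with no overlap. RPKM adds no separate check, because for a single gene it gives the total-count ratio. A difference between reporter signal and Kitl transcript, or between the lineages in transcript per cell, stays open and was not tested.

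Replicate 2 of tomato+ cTEC held endothelial transcripts, with all 11 pan-endothelial genes tested above both other libraries. Erg, the remaining member of that list, fell under the abundance cut in tomato+ VEC and was left out. Expression by the cTEC of the group is argued against, because the median gene was 33.5 times the higher of the other libraries. RNA of the mean makeup of tomato- VEC is argued against by 7 venous genes, whose median reached 0.000553 of the predicted level. Of these, Nr2f2 (1.16) and Vwf (0.507) were nearer to it or above. The pan-endothelial excess had a median of 3.84% of the level in tomato+ VEC (quartiles 3.26 and 4.89). RNA of tomato+ VEC was first taken as the source, and the same venous genes were set against it only afterwards. Their median was 0.00974 of the predicted level, with Vwf at 12.2 and Nr2f2 at 5.90 times. These genes had been chosen for being higher in tomato- VEC, and the prediction takes the mean makeup of tomato+ VEC. They argue against RNA of that mean makeup as the whole source, but cannot exclude RNA of a part of the tomato+ VEC. RNA of endothelial cells of another makeup, a part of either VEC group among them, stays open and was not tested, and the EpCAM+ CD31- gate should remove such cells.

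More genes were lower in both tomato+ gates (33) than independent lists give (8.16). Reads shared between the Ccl21 copies are argued against as the whole source, since 26 genes were lower in both without them, against 7.73 for independent lists. Leukocytes in both tomato- gates, which the lineage-negative sort of all groups and the EpCAM+ gate of mTEC should remove, cannot be told apart from expression in the stroma: the highest of the medians of the myeloid, thymocyte and B cell lists was 0.0594 of Rac2 in tomato- VEC, but Lyz2, Fcer1g, Cd68 and Lck (14.4 ± 24.9, 15.04 ± 8.44, 14.3 ± 9.32 and 15.9 ± 15.5 CPM; SD, n = 3) had means above the 7.76 CPM of Rac2. Of these, Lyz2 and Fcer1g had lower means in both tomato+ gates, while Cd68 had higher ones (30.4 CPM in tomato+ VEC, and 13.9 against 7.15 in TEC), Lck was at 13.8 CPM in tomato+ VEC and at 19.2 against 15.8 in TEC, none passed in either contrast, and Ptprc had 0 counts in tomato- VEC. The median was first taken over the 3 lists together (0.00938) and then per list, because the lists mark different cells, which changed the reading from against leukocytes to open; a programme shared by tomato- cells of both lineages also stays open and was not tested.

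For the genes called in the same direction in both contrasts, the larger of the numbers higher and lower was taken for each other split, because a split and its mirror image were counted once. Of 100 drawn splits 1, the real one, gave as many genes as the 13 higher in both, and 1 as many as the 33 lower in both. The highest other was 10 for each, the number lower in VEC and higher in TEC, from the split that exchanged the TEC groups. Without it the highest was 1. The other splits call few genes in at least 1 contrast, which follows once the groups differ at all. They speak only against libraries interchangeable within each lineage, and they do not test whether the overlap exceeds that of lists with real changes. For the pairwise comparisons the 10 splits of 6 libraries are too few for a share under 0.05. In each, 1 of 10 splits, the real one, gave as many genes: 244 against a highest other of 10 in VEC, 1158 against 2 in TEC and 3239 against 0 between the tomato+ populations.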

How the results depend on the processing

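The fit without cTEC replicate 2 for the VEC comparison and the counts with identical symbols taken once were chosen after seeing the data, and all other alternatives were planned. Where a count moved, the cause was not tested. The VEC comparison gave 244 genes, and 1253 by DESeq2, 601 by voom, 473 on RPKM, 112 with only its 6 libraries (71 shared), and 174 to 394 with a library left out (394 without tomato+ VEC replicate 3). Without cTEC replicate 2 it gave 205. The TEC comparison gave 1158 genes, and 1973 by DESeq2, 2219 by voom, 2530 on RPKM, 2487 with only its 6 libraries, and 428 to 702 with a library left out. The comparison of the tomato+ populations gave 3239, between 2375 and 4188 under every alternative run. The difference between the contrasts gave 456, 1418 by DESeq2 and 159 to 491 with a library left out. It fell by over 1.5 times without any mTEC library, cTEC replicate 1 or 3, or tomato- VEC replicate 1. Genes higher in both numbered 13, 71 by DESeq2 and 8 to 23 with a library left out. Genes lower in both numbered 33, 118 by DESeq2 and 20 to 35 with a library left out. With identical symbols taken once these were 13 and 29. DESeq2 also had the largest share of false calls in the simulations, but these used the spread estimates of edgeR and may favour it. They do not settle which count is nearer the truth.

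With the replicate number as a block the counts were 178, 814 and 2869 in the pairwise comparisons, 269 for the difference, and 12 and 25 for genes higher and lower in both. The numbers were not taken to pair the libraries, because 0 of 18 same-number correlations were above 0.1 (-0.0137 to 0.0687). As a hint from the data, 8 of 12 libraries had their highest correlation with their own number, 4 of them in each of the 3 other groups. Same-number correlations had a mean of 0.0186 against -0.00931 for different numbers, and 3 of 216 assignments of the numbers, the real one among them, gave as high a mean (chosen after seeing the data), so that a small shared effect stays open. The block ended the calls of Alox5ap, Lpl, Lrrc2 and Sox11 in VEC, of Cd3e, Cd8a, Darc, Fosb, Itgb2 and Plcb2 in TEC, and of Cd8a between the tomato+ populations, and added Hspa1b in VEC. Under the block 1, 0 and 1 list calls of the VEC, TEC and tomato+ comparisons were lost and 0, 0 and 1 gained. An estimated correlation ended 8 of 11, 7 of 15 and 7 of 19 list calls. Fry ended 6, 0 and 0 and added 0, 7 and 5, and relative log expression scaling ended 0 and added 0, 0 and 1.

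Of the named genes 41, 63 and 73 were called, and 26, 42 and 71 of them stayed called whichever library was left out. The direction of a named gene turned for values that had not passed: Enpep in VEC (0.05) was -0.000616 on RPKM, and -0.11 and -0.62 without tomato+ VEC replicates 2 and 3, and -0.50 and -0.11 without tomato- VEC replicates 1 and 2, with 1.43 the highest. Pecam1 in TEC (2.29) was -0.38 by voom and -2.79 without cTEC replicate 2, with 2.96 the highest. In VEC voom ended the calls of Ccl21c and its copies, Cd74, Hspa1a, Rgs4 and Ccdc80, and RPKM those of Ank3, B4galnt1, Rac2 and Sox11. In TEC voom ended Darc, Dclk1, Hspg2, Klf2 and Nrp1, and RPKM ended Bst1, Darc, Hspg2 and Lyve1. Leaving out the low-count filter ended Cd3e and Plcb2 in TEC. Named genes that had not passed were also gained: in VEC 9 by DESeq2, 6 by voom and 3 on RPKM. In TEC these gains were 4, 6 and 6. With only 6 libraries 16 named calls were lost in VEC, Rac2, Rgs4 and Ccdc80 among them, against 2 in TEC (Hspg2 and Lyve1) and 2 between the tomato+ populations (Acvrl1 and Pecam1). At total counts of 8388869 to 11807130 per library, edgeR recovered at most 2% of 2-fold changes in the simulations.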

Other observations

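Genes that went opposite ways between the tomato+ and tomato- gates of VEC and of TEC were chosen after their values were seen. In TEC these gates also differ in cortex against medulla. Of 10 genes lower in tomato+ VEC and higher in tomato+ cTEC (4.37 for independent lists), Ctsl, which encodes cathepsin L, stood at 1020 ± 120 against 5718 ± 857 CPM in VEC and at 7214 ± 1174 against 1810 ± 869 CPM in TEC (SD, n = 3). Apoe, apolipoprotein E, stood at 481 ± 41.9 against 2990 ± 867 CPM in VEC and at 1354 ± 242 against 463 ± 282 CPM in TEC. The difference between the contrasts passed for Ctsl and Apoe (edgeR adjusted p = 0.000286 and 0.00288). Genes called in opposite directions in the same fit were all but bound to pass this test, so it adds no separate support. Bmp4, Vldlr, Efemp1 and Sirpa were among those that went the same way. Of 7 genes with the opposite pattern (4.28 for independent lists), Fas, the death receptor, stood at 304 ± 126 against 35.4 ± 20.1 CPM in VEC and at 63.02 ± 22.9 against 356 ± 81.2 CPM in TEC, and Pitpnc1 at 353 ± 71.3 against 117 ± 26.8 and at 26.9 ± 3.12 against 303 ± 88.6 CPM. Differences between the contrasts passed for both (edgeR adjusted p = 0.00178 and 0.000143), with the same limit from the way they were chosen.

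Several lists were not called in any pairwise comparison. Over VEC, TEC and the tomato+ populations, camera adjusted p was 0.466, 0.177 and 0.199 for Wnt response genes, 0.466, 0.862 and 0.909 for complex I subunits, and 0.706, 0.236 and 0.0656 for cholesterol synthesis genes. It was 0.713, 0.0617 and 0.966 for myeloid genes, 0.706, 0.139 and 0.558 for platelet genes, and 0.824, 0.0932 and 0.0630 for the sorting genes. Among the cholesterol synthesis genes, Sqle, Lss and Sc5d were lower in tomato+ VEC than in cTEC (edgeR adjusted p under 0.05), and Insig1 was higher in cTEC than in mTEC. In the VEC comparison the 21 lists without a call ran from 0.129 to 0.861, in TEC 17 from 0.0617 to 0.910, and between the tomato+ populations 13 from 0.0582 to 0.966. Of the B cell genes Blnk, also expressed outside B cells, stood at 6.82 ± 2.29 CPM in cTEC against 361 ± 66.5 CPM in mTEC (SD, n = 3; log2 -5.73, edgeR adjusted p = 0.000622), and Cd79b at 0.837 ± 1.45 against 25.1 ± 15.6 CPM without passing (edgeR adjusted p = 0.131).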
